A study of Rattus norvegicus with 8 samples.

How the data were processed

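RNA was measured by sequencing in rat embryonic hippocampal neurons grown for 10 to 14 days in microfluidic chambers, devices in which axons grow through narrow grooves into a compartment separate from the cell bodies. Soluble oligomers of the amyloid peptide Abeta(1-42), or vehicle, were applied to the axonal compartment for 24 h, and libraries were made with a TruSeq kit from RNA of the axonal and of the cell body compartment, per the labels' protocols. The 8 samples fall into 4 groups of 2 (axons Abeta, axons vehicle, soma Abeta, soma vehicle), with groups and replicate numbers taken from the sample titles. Nothing in the labels says that the duplicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

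Per the submitters' processing notes, Trim Galore, TopHat2, SAMtools and DESeq2 were used, and no version of them was given. The genome build, the annotation and the counting program are not given in the sources used here, so no coordinates are printed. The data analysed here are 2 tables of the authors' own comparisons, 1 per compartment, each with 26405 Ensembl rat genes. Per the file headers, each holds a mean normalized count over the 4 libraries of a compartment (a signal the authors made by dividing gene counts by size factors), a log2 fold change with its standard error (log2 values from the authors), a Wald score deposited with them, and the deposited p-value with its Benjamini-Hochberg adjusted value. The tables hold no column per library. The Wald score equals the log2 fold change divided by its standard error, and the p-value is the two-sided normal p of that score. Deposited log2 fold changes lay closer to 0 than the log2 ratio of the recovered side sums (described below) in 100% of genes with reads on both sides and a ratio of at least 0.5 in size. The median of deposited over recovered values was 0.519 in axons and 0.213 in soma for means of 1 to 10, and 0.949 and 0.752 for means of 100 to 1000. Deposited values were thus drawn toward 0, more so in soma and in genes with few reads. Since genes were kept by the size of their recovered ratio, which counting noise can give, this does not show that true changes are understated. The test of the difference between compartments takes the values as deposited.

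The file headers do not say which treatment is the numerator, and nothing in the values can settle it. Every fold change is therefore given with its sign as deposited: a gene is said to lie on the positive side where the deposited log2 fold change is above 0 and on the negative side where it is below 0, and neither side is named as Abeta or vehicle. The main result of each compartment is the authors' adjusted p under 0.05, as fixed before the data were examined for the case of deposited comparisons alone, so no test of counts was run here. In the axonal table, adjusted p-values are given to 1321 of the 23879 genes with reads, all with a mean normalized count of at least 44.8. In the somatic table, all 18995 genes with reads have an adjusted p.

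Gene symbols came from the tables (18310 genes) and, for 1837 more, from the RefSeq gene table of assembly GRCr8 through the Entrez identifier. The other 6258 identifiers carry no symbol here and were not named. Both Ensembl genes named Ncan, and genes with LOC symbols or many near-identical copies, may share reads, and their values are uncertain.

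The reads of each library were recovered from the deposited means, which carry up to 15 significant digits. A mean is the sum of 4 whole read counts, each multiplied by a unit that is fixed for its library, and genes with a single read in the table give these units. The sign of their fold change gives the side of the library. A match was accepted only within the rounding of the last digit. For means under 100, 100% of values had exactly 1 solution in both tables, and 0% of shifted decoy values had any. For means from 500 to 999, decoys had a solution in 12.8% of cases in axons and 6.85% in soma, so these values are less certain, and means above 1000 were not solved. On simulated means, 7593 of 7593 values of a table with depths like the axonal one and 7804 of 7808 of a table with depths like the somatic one had exactly 1 solution, the right one. The recovered libraries cannot be matched to a sample title. They are named here by their side and a number (1 for the larger size factor), are given as values per library or sums per side, and enter no test between treatments.

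The recovered size factors were 1.32 and 1.28 for the positive-side axonal libraries and 0.952 and 0.740 for the negative-side ones. In soma they were 2.97 and 0.297 on the positive side and 3.74 and 0.320 on the negative side. Reads in the recovered genes, which leave out the most abundant identifiers, numbered 231854 to 425420 per axonal library and 262971 to 3656302 per somatic library.

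Lists of 33 gene groups (pathways, organelles, synaptic genes and markers of the cell types such a culture could hold) were fixed before the data were examined. Each was tested with cameraPR of limma 3.58.1 in R 4.3.3 on the authors' Wald score, with a preset correlation of 0.01, at least 5 tested members and Benjamini-Hochberg adjustment over the lists. The estimated correlation that camera can use was not run. It needs values per library, and the recovered libraries, known by side but not by sample or treatment, were kept out of tests. A preset correlation of 0.05 was the alternative. On simulated scores drawn independently for the 23879 axonal genes, 2.5% of 640 list tests without a change had p under 0.05. A list moved by 1 SD was found in 19 of 20 runs. Those scores held no correlation between genes and no trend with abundance, so they do not show how the test behaves on the real scores. The difference between compartments was tested per gene with z, the difference of the log2 fold changes divided by the root of the summed squares of their standard errors, a two-sided normal p and Benjamini-Hochberg adjustment. For that test on 18406 simulated genes, 41 of 200 genes changed by 2 on the log2 scale and 191 of 200 changed by 4 were recovered. Beside them 0 and 11 unchanged genes were called, and 0 genes were called when none was changed. The changed genes were drawn only from genes well covered in both compartments, so these rates do not hold for genes with few reads. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0 were used for these steps.

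Named genes follow a rule written before the data were examined: among called genes with a symbol, the 12 with the smallest adjusted p in each direction, up to 4 called members per list, the 5 with the smallest p for the difference between compartments, and Atf4, Ddit3, App, Actb, Gap43, Rhoa, Map2, Gfap and Snx4 whatever their values. The clause of that rule on libraries that do not overlap held for all 161 called genes whose reads were recovered and could not be checked for the other called genes. A gene that the rule names is not reported here. Alternatives covered the threshold, a 2-fold minimum, the genes adjusted together, the Benjamini-Yekutieli adjustment, and for lists the ranks, the correlation, the genes compared with and the statistic. Tests that leave out replicates, use a replicate block, another normalization or another pseudocount were not run. The recovered libraries, known by side but not by sample or treatment, were kept out of tests. Some values per side are also given with a recovered library left out, without a test.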

Results

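The data compare RNA of the axonal and of the cell body compartment (soma and neurites around it) of hippocampal neurons. Soluble Abeta(1-42) oligomers or vehicle had been applied to the axons alone for 24 h. Each of the 4 groups had 2 samples. The authors' deposited tables give 1 comparison of treatments per compartment, without naming the numerator, so signs are as deposited and no value below says whether Abeta raised or lowered a transcript. Reads were found for 23879 genes in axons and 18995 in soma. The 20 most abundant identifiers, of which 1 had a gene symbol, held 53.1% of the summed means in axons and 70.6% in soma.

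The first comparison asks which transcripts of the axonal compartment differ between the treatments. The genes of smallest adjusted p lay on the positive side, and astrocyte, fibroblast and cholesterol synthesis genes were among the lists of smallest adjusted p there (cameraPR). The median log2 fold change of fibroblast markers was 1.34 for the 14 with a mean of at least 10, but 0.28 for all 21 measured. In the authors' deposited table, Cp (ceruloplasmin, a copper-carrying ferroxidase; ENSRNOG00000011913) had a log2 fold change of 3.54 (SE 0.45, adjusted p = 5.54e-12), or 11.7-fold. Chi3l1, a secreted chitinase-like protein (ENSRNOG00000003312), stood at 3.63 (SE 0.49, adjusted p = 7.31e-11) in the authors' deposited table, and Sparc, a matrix-binding glycoprotein (ENSRNOG00000012840), had an 8.01-fold difference to the same side (SE 0.40 on the log2 scale, adjusted p = 3.78e-11). The intermediate filament genes Vim and Gfap, both strongly expressed by astrocytes, stood at 2.53 (SE 0.37, adjusted p = 2.81e-09) and 2.27 (SE 0.44, adjusted p = 2.91e-05) there. Gas6 (a ligand of receptor tyrosine kinases), C3 (complement component) and Cst3 (a protease inhibitor) had log2 fold changes of 2.97, 2.80 and 2.63 in the authors' deposited table. The other genes of smallest adjusted p on that side were Scd1 (fatty acid desaturase, 2.56), Fbln1 (matrix protein, 2.59), Gsta1 (glutathione transferase, 3.75) and the proteoglycan Ncan, at 2.06 and 2.02 for its 2 identifiers, per the authors' deposited table.

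By the authors' adjusted p under 0.05 (DESeq2), 304 of 1321 genes were called in axons, 116 on the positive and 188 on the negative side, and all 304 had at least a 2-fold change. Symbols were at hand for 110 of the positive and 14 of the negative calls. After subtracting the median fold change of genes well expressed in soma, 0.44, there were 67 positive and 221 negative calls, of which 62 and 26 had a symbol. The count fell to 81 when p-values were adjusted over the 8032 genes with a mean of at least 10, and to 52 when adjusted over every gene with reads. Those adjustments gave 71 and 50 positive calls and 10 and 2 negative ones.

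**Figure D1:**
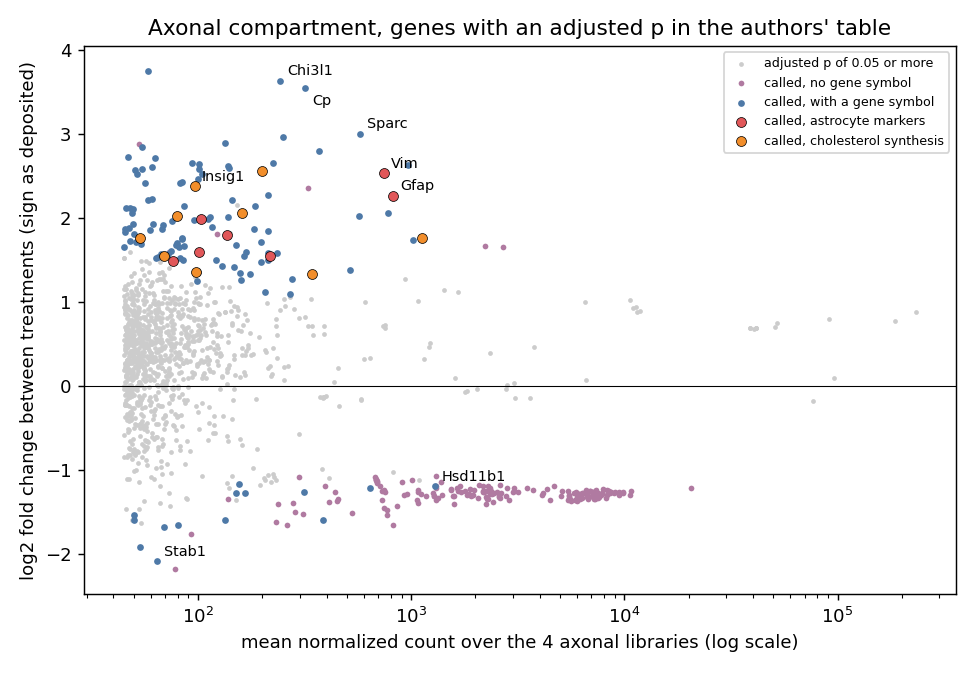
Log2 fold change between treatments (sign as deposited) against mean normalized count (log axis) for the 1321 axonal genes with an adjusted p in the authors' deposited table; each point is a gene, coloured by call, symbol and list. Called genes with a symbol lie mostly on the positive side (110 against 14, or 62 against 26 after subtracting the median of 0.44), and 174 called identifiers without a symbol lie on the negative side around a median of -1.27.

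The recovered reads show the size of these differences library by library. Cp had 575 and 603 normalized counts in the positive-side libraries and 29.4 and 60.8 in the negative-side ones. Chi3l1 had 594 and 308 against 38.9 and 23.0, Vim 1286 and 1264 against 225 and 192, and Gfap 1228 and 1530 against 158 and 375 normalized counts. Of the 7851 recovered genes with a mean of at least 10, 3890 had sides that did not overlap (49.5%, where 33.3% arises by chance with 2 against 2). All genes share the same libraries, so a difference between libraries can move many of them together. Size factors also separated the sides completely (1.32 and 1.28 against 0.952 and 0.740). The excess therefore cannot tell treatment from other differences between these libraries.

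**Figure D2:**
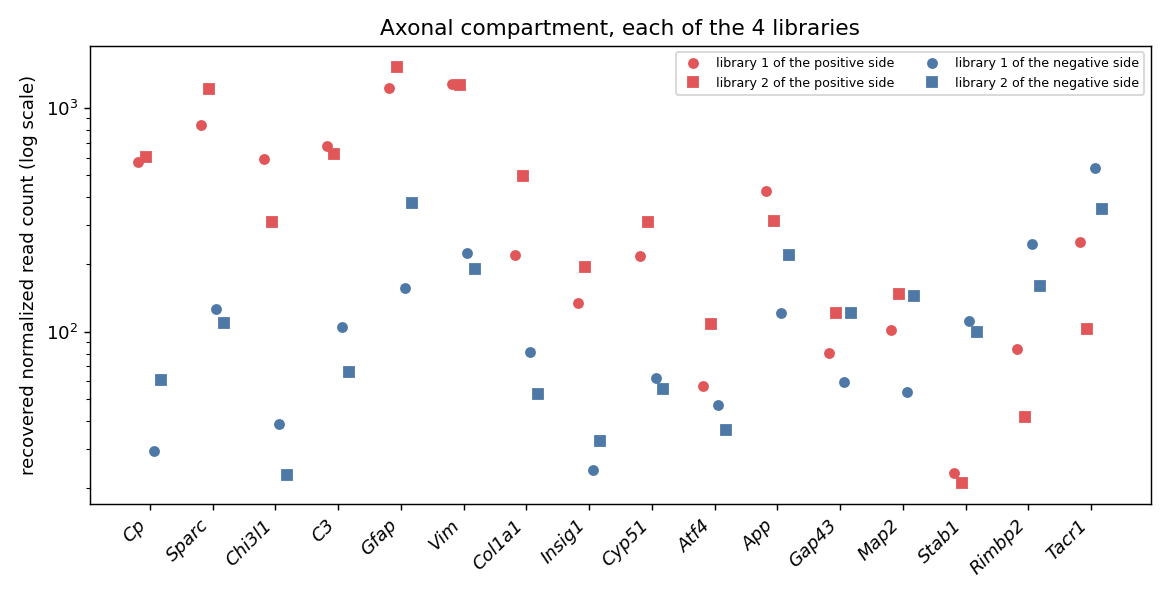
Recovered normalized read counts (log axis) of 16 named genes in each of the 4 axonal libraries, with colours for the side of the deposited fold change and shapes for the library; each point is 1 library. Cp lies at 575 and 603 on the positive side and at 29.4 and 60.8 on the negative side, while the libraries of Gap43 and Map2 overlap.

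Among cell type markers, 7 of the 19 measured astrocyte genes were called on the positive side (8 adjusted over the list alone) and 0 on the negative side. Beside Vim and Gfap these included Aldoc at 1.99 (SE 0.54) and Glul, the glutamine synthetase, at 1.80 (SE 0.46) on the log2 scale in the authors' deposited table. Other astrocyte genes had fold changes below 0 that were not called, among them Sparcl1 at -0.71, Slc1a2 at -0.82 and Slc4a4 at -0.77 in the authors' deposited table, named after their values were seen. Of 21 fibroblast and meningeal markers, 6 were called positive (7 adjusted over the list alone), with Col1a1 at 2.28 (SE 0.50) and Col1a2, the other chain of type I collagen, at 2.65 (SE 0.63) in the authors' deposited table. Another 9 of the 21 had fold changes below 0 that were not called, among them Fbn1 at -0.38, Dcn at -0.57, Lum at -0.59 and Igf2 at -1.25 in the authors' deposited table, named after their values were seen. The astrocyte list (adjusted p = 5.54e-15) and the fibroblast list (adjusted p = 5.36e-11, cameraPR) lay above other genes. In soma, 18 of the astrocyte and 14 of the fibroblast markers had a mean of at least 10. Markers of microglia (adjusted p = 0.0158), endothelium and mural cells (0.0276) and interneurons (0.0271) lay lower than other genes in axons (cameraPR). At a preset correlation of 0.05 their adjusted p was 0.0695, 0.0868 and 0.0868. They had 0 called members, but only 1 of 19, 0 of 14 and 1 of 17 had an adjusted p and could be called. Among astrocyte markers 12 of 19 could. Oligodendrocyte (0.656) and erythrocyte (0.268) markers did not pass.

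Genes of cholesterol and fatty acid synthesis formed the list with the smallest adjusted p (1.26e-20, cameraPR): 9 of 24 measured members were called on the positive side, over the 1321 genes with an adjusted p and adjusted over the list alone. Insig1, a sterol-sensing regulator, stood at 2.38 (SE 0.52, adjusted p = 0.000247) and Cyp51, a demethylase of sterol synthesis, at 2.06 (SE 0.46, adjusted p = 0.000329) in the authors' deposited table. The identifier LOC100912469, named Scd2 in RefSeq, stood at 1.76 (SE 0.37) there. Of 27 oxidative stress genes, 3 were called on the positive side (2 adjusted over the list alone), which were the metallothionein Mt2A at 2.42, Sod2 at 1.66 and Prdx6 at 1.73 in the authors' deposited table (list adjusted p = 2.69e-12). Of 21 glycolysis genes, 3 were called, namely Aldoc, Pkm at 1.59 and Aldoa at 1.43 in the authors' deposited table (list adjusted p = 2.63e-07, 3 adjusted over the list alone).

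Lists of protein folding, translation and stress also lay on the positive side, with few called members. Heat shock proteins (adjusted p = 3.94e-09), endoplasmic reticulum chaperones (8.90e-08), translation factors (2.19e-07) and the integrated stress response (7.46e-06) passed cameraPR, each with 1 called member over the 1321 genes with an adjusted p and 0 adjusted over the list alone. These members were LOC100362895 (Hsp90aa1 in RefSeq) at 1.12, Canx at 1.35, Eif4g2 at 1.28 and the amino acid transporter subunit Slc3a2 at 1.65 on the log2 scale in the authors' deposited table. Only 6 of 21, 7 of 21, 17 of 48 and 6 of 34 genes of these lists, in the same order, had an adjusted p and could be called. Atf4, the transcription factor of the integrated stress response, had a log2 fold change of 0.91 (SE 0.58, adjusted p = 0.288) in the authors' deposited table and was not called, with 57.4 and 109 against 47.3 and 36.5 normalized counts per library. Its target Ddit3 stood at 2.22 (SE 1.02) on a mean of 7.47 counts, and the authors' deposited table gives it no adjusted p.

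Synaptic and somatic lists did not pass. The presynaptic list (45 genes, median log2 fold change -0.01, adjusted p = 0.362), the postsynaptic list (32 genes, 0.22, adjusted p = 0.131) and the list of nuclear and somatic transcripts (15 genes, 0.23, adjusted p = 0.192) had 0 called members. Only 18, 9 and 3 of their members, in that order, had an adjusted p and could be called. Gap43, a growth cone protein, stood at 0.15 (SE 0.53) and Map2, a dendritic microtubule protein, at 0.32 (SE 0.54) in the authors' deposited table. App (1.07, SE 0.45, adjusted p = 0.0663), Actb (1.00, SE 0.43, adjusted p = 0.0777) and Rhoa (0.98, SE 0.55, adjusted p = 0.217) were not called in the authors' deposited table. Snx4 stood at 0.14 (SE 0.80) there, without an adjusted p. Among 36 Alzheimer disease genes, Clu (1.58) and Lrp1 (1.10) were called in the authors' deposited table, and 0 adjusted over the list alone (list adjusted p = 0.000547). That list did not pass among genes with a mean of at least 10 (adjusted p = 0.0958) or with a somatic mean of at least 10 (0.0822). Of 32 retromer and endosomal genes, Lamp1 (2.02) was called both ways in the authors' deposited table (list adjusted p = 9.75e-05).

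Cytoskeletal genes (adjusted p = 0.000145), motor proteins (0.000111), RNA binding proteins (0.00116), oxidative phosphorylation (9.48e-06), proteasome (0.000307), vacuolar ATPase (0.00369, with Atp6v0a1 called at 1.25 in the authors' deposited table), splicing factors (4.92e-05), ribosomal proteins (0.000213), mitochondrial ribosomal proteins (0.0155), immediate early genes (0.0198) and interferon genes (0.0445) also lay on the positive side of other genes. Several of these calls did not hold in other settings. Among genes with a mean of at least 10, the adjusted p was 0.0591 for cytoskeletal genes, 0.0684 for RNA binding proteins, 0.0597 for the proteasome, 0.0591 for vacuolar ATPase, 0.592 for mitochondrial ribosomal proteins and 0.253 for immediate early genes. Among genes with a somatic mean of at least 10 it was 0.0543 for cytoskeletal genes, 0.0816 for RNA binding proteins, 0.817 for mitochondrial ribosomal proteins and 0.161 for immediate early genes. At a preset correlation of 0.05 it was 0.0569 for ribosomal proteins, 0.151 for mitochondrial ribosomal proteins, 0.0868 for immediate early genes and 0.183 for interferon genes, which also missed the threshold with ranks (0.351) and with the log2 fold change (0.216). The interferon list had a median log2 fold change of -0.18, opposite in sign to its mean of 0.06 and its positive test, and 12 of its 14 genes with a mean of at least 10 lay above 0. Cytoskeletal and Alzheimer disease genes with a mean of at least 10 had medians of 0.32 and 0.26. Cell cycle genes lay on the negative side (adjusted p = 0.0158, but 0.0927 at a preset correlation of 0.05 and 0.160 among genes with a mean of at least 10), and apoptosis genes did not pass (0.312, median -0.07, mean 0.12). Mitochondrially encoded genes had 0 matched members. In all, 26 of 32 tested lists passed, 22 positive and 4 negative, and 13 of these, all positive, passed in each of the 6 settings tried. None of the settings matched lists by abundance, and median axonal fold changes rose with somatic mean, from -0.006 at 10 to 50 to 0.69 above 1000. Genes with a somatic mean of at least 100 had a median axonal log2 fold change of 0.44 (2683 genes), and 26 of 31 list medians lay above 0 but 20 above that shift. Of the 13 lists, splicing factors (0.46), glycolysis (0.47), retromer (0.51), oxidative phosphorylation (0.52) and motor proteins (0.52) had medians little above it. The rest lay between 0.57 (translation factors) and 1.44 (astrocyte markers). All of these list results stand beside a difference in another group of genes: the 5473 genes with axonal but no somatic reads took 2.80% and 1.25% of recovered reads in the positive-side libraries and 5.59% and 4.62% in the negative-side ones.

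**Figure D3:**
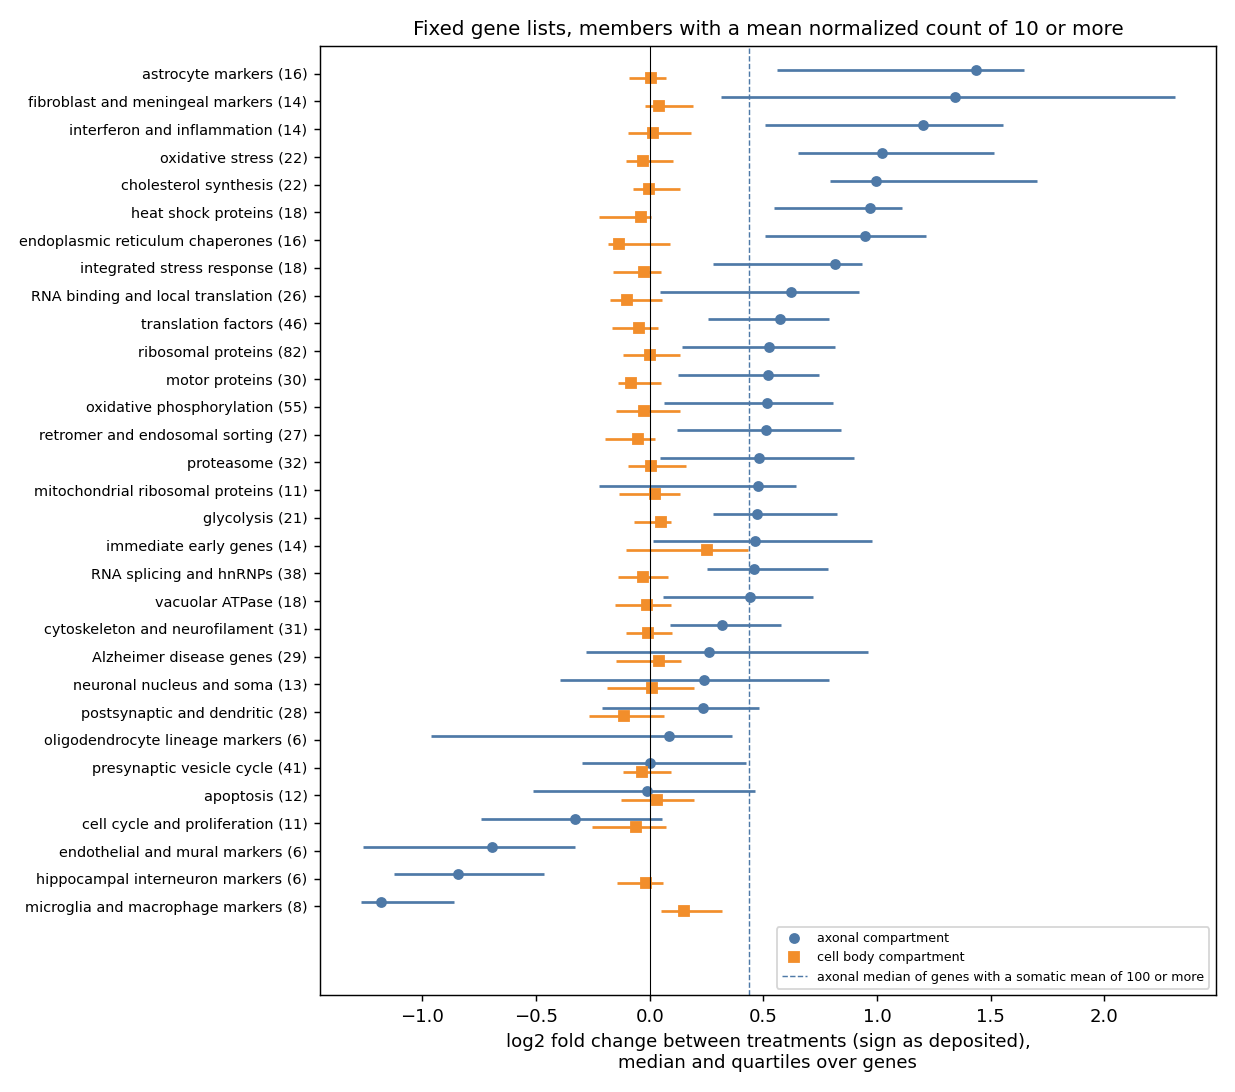
Median (point) and quartiles (line) of the log2 fold change between treatments, sign as deposited, over the members of each fixed list with a mean of at least 10, for the axonal (blue) and cell body (orange) compartments; the dashed line marks the axonal median of 0.44 of genes well expressed in soma. Astrocyte markers have an axonal median of 1.44 and presynaptic genes one of 0.00.

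The negative calls in axons were of another kind. Stab1 (a scavenger receptor) stood at -2.08 (SE 0.55, adjusted p = 0.00399) and Rimbp2 (a presynaptic scaffold) at -1.60 (SE 0.51) in the authors' deposited table. Lama1 (-1.27), Hic2 (-1.27), Tacr1 (the substance P receptor, -1.26), Cry2 (a clock repressor, -1.17), Gpr83 (-1.59), Hsd11b1 (-1.19), Rn5s (5S ribosomal RNA, -1.91), LOC100364265 (Rpl19l4 in RefSeq, -1.59) and LOC100362110 (-1.21) were also among them in the authors' deposited table. Several of these named calls had far higher mean normalized counts in axons than in soma. The axonal and somatic means were 312 and 12.7 for Tacr1, 1289 and 140 for Hsd11b1, and 166 and 22.2 for Hic2. Cry2 had similar means (156 and 152), and of those named here only Stab1 had a lower one in axons. Named calls far higher in axons may share the background source weighed below for calls without a symbol, which was not tested for them. Another 174 negative calls had no symbol. Their median log2 fold change was -1.27 with an SD of 0.12 over identifiers, and they held 31.4% of the summed means in axons and 0.841% in soma.

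The second comparison asks whether cell bodies differed when the axons alone were treated. No transcript was called: 0 of 18995 genes passed the authors' adjusted p under 0.05 (DESeq2), the smallest adjusted p was 1.00, and 2 genes, both without a symbol, had an unadjusted p under 0.05. In the authors' deposited table Cp stood at 0.09 (SE 0.58), Vim at 0.08 (SE 0.49), Gfap at 0.06 (SE 0.45), Atf4 at -0.12 (SE 0.47) and Gap43 at -0.06 (SE 0.48). Immediate early genes (23 genes, median 0.23) and microglial markers (19 genes, median 0.15) lay above other genes, each with adjusted p = 0.00625 (cameraPR) and 0 called members, over all genes or adjusted over the list alone, and each with adjusted p = 0.101 at a preset correlation of 0.05. The other 29 of 31 lists had adjusted p of at least 0.789.

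Each side of the somatic comparison held a deep and a shallow library (size factors 2.97 and 0.297 on the positive, 3.74 and 0.320 on the negative side), so values were also taken within a depth. Over 2564 recovered genes with a mean of at least 100, the log2 ratio of the sides had an SD of 0.251 between the deep libraries and 0.365 between the shallow ones, against 0.996 and 1.08 between the depths of a side. A 2-fold difference was seen for 1 gene in the deep pair, for 25 in the shallow pair and for 0 in both. Across genes, which are not independent replicates, the differences of the 2 pairs had a Pearson r of 0.181 and a Spearman rho of 0.191. Of 17 microglial markers with a mean of at least 10, 14 lay on the positive side in the deep pair (median 0.39) and 13 in the shallow pair (median 0.22). Immediate early genes had a median of -0.07 in the deep pair (6 of 18 positive) and 0.56 in the shallow pair (13 of 18), so their shift was not seen at both depths.

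The third comparison asks whether the axonal and somatic differences were themselves different. Of 18406 genes tested in both, 6 passed the test of the difference, all with the higher log2 fold change in axons, where deposited fold changes were drawn less toward 0 than in soma. The gene of smallest p was Chi3l1, with an axonal minus somatic difference of 3.82 (SE 0.71, adjusted p = 0.00164), followed by Cp at 3.45 (SE 0.73, adjusted p = 0.0152). Gsta1, Gas6, Sparc and an identifier without a symbol also passed, each with adjusted p = 0.0152, while Vim and Gfap did not. Over all genes the axonal and somatic fold changes had a Pearson r of -0.00172 and a Spearman rho of -0.0126. Over the 302 genes called in axons and measured in soma, r was 0.625, with 0.170 among the 122 with a symbol and 0.310 among the 180 without. No overlap of calls could be tested, since soma had 0.

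The abundance of transcripts in axons and soma could be set side by side only from the authors' means over both treatments, as a description, since the 2 tables were normalized separately. Fibroblast markers were the list highest in axons, with a median log2 ratio of axons over soma of 1.57 (11 genes with a mean of at least 10 in both, scaled to the median gene). These means pool sides and libraries in which fibroblast markers differed, with a median log2 fold change of 1.34 between the axonal sides and a median log2 ratio of -1.24 between deep and shallow somatic libraries. Cytoskeletal and neurofilament genes (-1.08), vacuolar ATPase (-1.05), oxidative phosphorylation (-0.92) and ribosomal proteins (-0.84) lay lowest. Presynaptic (-0.47), postsynaptic (-0.48) and astrocyte (-0.73) lists lay between them. So did nuclear and somatic transcripts (-0.27), above the presynaptic list. These ratios therefore do not show that the axonal compartment held RNA of axons alone. Reads were seen only in axons for 5473 genes and only in soma for 589. Those 5473 genes held 11909 and 5268 recovered reads in the positive-side axonal libraries and 16398 and 10710 in the negative-side ones. These are few reads per gene, so a gene seen only there need not be an axonal transcript.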

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

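The tests of explanations in this part were chosen after the results were seen. The 6 genes whose difference between treatments was larger in axons than in soma, by the test of the difference itself, were Chi3l1 (axonal minus somatic log2 fold change 3.82), Cp (3.45), Gsta1 (4.11), Gas6 (2.87), Sparc (3.07) and the unnamed ENSRNOG00000050464 (5.14), which had 44 and 61 reads in the positive-side axonal libraries and 0 and 0 in the negative-side ones. Their adjusted p ranged from 0.00164 to 0.0152.

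Of these genes, Sparc belongs to the fibroblast list and the others to no fixed list of cell markers; the pattern weighed here is the positive axonal fold changes of the astrocyte and fibroblast lists. A smaller share of background reads in the positive-side libraries would raise genes of like somatic abundance alike, and the tables argue against it as the whole cause: the median log2 fold change of 16 astrocyte markers, 1.44, exceeded the median of 10000 random lists matched by somatic mean by 0.96, and 95% of those lists lay between 0.13 and 0.83 (between -0.09 and 0.75 when matched by axonal mean). Only members with a mean of at least 10 entered these comparisons. Over all measured members the medians were 1.31 for 19 astrocyte and 0.28 for 21 fibroblast markers. The median of the 14 fibroblast markers that entered, 1.34, exceeded that of its own matched lists by 1.39. Of those lists, 95% lay between -0.57 and 0.38 (between -0.19 and 0.74 by axonal mean). From recovered reads and somatic means the excess was 0.97 for astrocyte markers, and 0.69 to 1.31 with each library left out, and 1.49 for fibroblast markers, and 1.47 to 1.79. For the astrocyte list alone, astrocyte RNA of the kind found in the cell body compartment was weighed too. The gain of 13 other markers abundant in soma had a median of 0.238 of what the gain of Vim and Gfap would require (0.168 to 0.354 with each axonal library left out). Agt, Slc1a2, Slc4a4, Sparcl1 and Fabp7 stayed at or under 0.0573 whichever axonal library was left out, so these markers did not rise along with Vim and Gfap. Gja1 gained 1.12 (0.932 to 1.30). The reference genes differed, with 0.784 for Gfap and a value above 1 for Vim. The number of markers under 0.25 rests on single libraries, since it was 7 of 13 with all of them but 5 without the shallower positive-side or the shallower negative-side library. Vim and Gfap were chosen after the results were seen and are positive calls themselves, so lower gains of other markers are partly built in. The somatic levels were means over deep and shallow libraries, and no somatic library was left out. These gains therefore cannot decide whether astrocyte RNA as in soma is the whole cause. Other numbers of fibroblasts or astrocytes in the axonal compartment, and a response of such cells or of axons to treatment, cannot be told apart. Each side is 1 treatment with 2 libraries. Of the positive calls, 13 were astrocyte or fibroblast markers. The response to treatment was not tested separately and stays open.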

How the results depend on the processing

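Alternatives added after seeing the data were the shifted fold changes, the restriction to named genes and the lists among genes with somatic reads. The axonal count of 304 calls became 69 at an adjusted p under 0.01, 61 with the Benjamini-Yekutieli adjustment, 81 with a mean of at least 10, 52 with no filter and 124 with named genes alone. The last leaves out the 180 called identifiers without a symbol, and the others follow from a stricter threshold or adjustment, or from the number of genes adjusted together. It stayed within 1.5 times at 0.1 (362), with a 2-fold minimum (304) and after subtracting the median of expressed genes, 0.44 (288), where the split turned from 116 positive and 188 negative to 67 and 221. All 304 calls already had a 2-fold change, so that minimum could not lower the count. The somatic count was 0 in all 6 alternatives. The difference between compartments gave 6 to 8 genes, including the same 6 each time. The correlation of fold changes moved from -0.00172 to 0.0495 with a mean of at least 10 in both and 0.0262 for the Wald score, the cause of which was not tested. Among called genes it was 0.625. Part of this lay between called genes with and without a symbol, since r was 0.170 and 0.310 within them. The unnamed negative calls also had a negative median in soma, -0.35. Genes at least 4-fold higher in axons fell from 4084 of 18406 (1268 were 4-fold lower) to 236 of 7257 (472 lower) with a mean of at least 10 in both. That restriction takes out genes with few reads in a compartment, and what else contributed was not tested. Scaled to the median ratio, 4394 of 18406 genes were at least 4-fold higher in axons. Axonal lists passing numbered 26, but 16 with a mean of at least 10 (the cause was not tested), and 18 to 25 otherwise; the 2 somatic lists became 0 at a correlation of 0.05. No list changed direction where it was called. No paired analysis was possible by replicate number because no column carries a replicate number. A block by depth class, leaving out replicates, other normalizations and pseudocounts were not run in a test. The side of each recovered library is known but not its sample or treatment, and these libraries were kept out of tests. In axons, genes under a mean of 44.8 have no adjusted p.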

Other observations

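The tests of explanations in this part were chosen after the results were seen. Below the mean count at which the authors' deposited table gives adjusted p-values, 7 axonal genes passed when p-values were adjusted over all genes, all on the positive side and chosen here after their values were seen. They include the serine protease Prss23 (36 and 76 reads in the positive-side libraries, 0 and 0 in the negative-side ones), the interleukin 1 receptor Il1r1 (60 and 70 against 2 and 1 reads), the complement protease C1r (102 and 91 against 6 and 8), the growth factor midkine, Mdk (31 and 60 against 0 and 1), and the transcriptional regulator Id3 (28 and 78 against 1 and 2). Their adjusted p over all genes ranged from 0.00113 to 0.0434, and Clcn4 and an identifier without a symbol complete the 7.

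The 174 negative axonal calls without a symbol have nearly the same fold change, with a median of -1.27 and an SD of 0.12. Genes without any somatic read, which hold few transcripts of these cells, also lay on the negative side. Summed over 5473 such genes, the log2 ratio of positive over negative libraries was -1.27, while genes with a somatic mean of 200 to 1000 had 0.69. That sum is another measure than the median of deposited fold changes, which was -0.37 for these 5473 genes. The summed ratio depends on single libraries, being -1.94 without the deeper and -0.82 without the shallower positive-side library. On the summed scale the 36 unnamed calls with recovered reads, of the 174, moved alike, from -1.36 to -1.96 and -0.94. This is consistent with more background reads in the negative-side libraries, such as genomic DNA or reads without a gene of their own, as a candidate source of these calls. Among 139 unnamed identifiers chosen by abundance whatever their fold change (an axonal mean of at least 1000, at least 10 times the somatic one), 138 were called negative, and the SD of their fold changes was 0.137 of their median standard error. Reads counted for several near-identical copies would also give this, so the calls may not be separate events. Whether the background differs by treatment or by chance between 2 and 2 libraries was not tested. These sources were not tested for the negative calls with a symbol, such as Tacr1 and Hsd11b1, and stay open for them.

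The absence of calls in soma has a technical candidate explanation in the depth of its libraries. The spread of log2 ratios between the deep and shallow library of a side was 3.37 times that between sides within a depth class (both deep or both shallow), and the depth differences of the 2 sides were correlated across genes (r = 0.927), as a shared difference of library batches may give. Such a spread raises the authors' standard errors, and 2 of 18995 unadjusted p-values were under 0.05. Whether treatment of axons changed any somatic transcript stays open.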
